A study of Mus musculus with 4 samples.

How the data were processed

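Gene expression was measured by RNA sequencing in osteoclast precursor cells of wild-type C57BL/6 mice, per the labels, after 3 h with DKK1 (200 ng/ml) or PBS. The number in each sample name (precursor cells 1 or 2) was taken as the mouse, which gives 2 pairs. The pairing was checked on the values: deviations of same-numbered libraries from their group means correlated at 0.869 across genes, and principal component 1 (87.7% of the variance) parted precursor cells 1 from 2.

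The deposited count table holds whole-number counts per gene, without normalization; according to the submitters' processing notes reads were processed with fastp and aligned with HISAT2 to mm10, and the counting program and annotation are not given in the sources used here. If the counts were derived from coverage, they are rounded estimates and not reads. Per the file headers, the authors' deposited tables, 1 for each pair, give a log2 ratio of DKK1 over PBS from scaled counts of 1 library against 1. The p-value and FDR columns of the authors' deposited tables come from a test that is not stated, and their calls equal an FDR under 0.05 with an absolute log2 ratio of at least 1 for all 13253 and 13175 genes listed. The FPKM values in those tables were made by the authors, scaled to gene length and library size, and were not used here. The counts in the authors' deposited tables equal those of the count table (0 differing).

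Of 53801 genes, 26361 had a count and 17462 passed edgeR's filterByExpr, with 99.95% of all counts. Symbols shared by 2 or more gene IDs (125 symbols) were kept apart by ID. The main model was edgeR 4.0.16 quasi-likelihood (TMM scaling, not robust, legacy off) in R 4.3.3, with terms for precursor cells and treatment, which leaves 1 residual degree of freedom. All adjusted p-values are two-sided, by Benjamini-Hochberg, with a threshold of 0.05. The same model tested DKK1 against PBS and precursor cells 2 against 1. The p-values of both tests rest on the same residual spread, which edgeR shares across genes. It is how far the change with DKK1 differs between the pairs from 2 mice. No preparation was replicated, so the second test compares these 2 preparations. Differences within a pair are log2 CPM (counts scaled to library size) with a prior count of 2, and their correlations use CPM plus 1.

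The 32 gene lists, the named-gene rule and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, whose mixed test asks for change in either direction. Neither fry test compares a set with other genes. The lists were canonical Wnt targets, Wnt receptors and DKK1-binding proteins, osteoclast genes, repressors of osteoclast differentiation, NF-kB and inflammatory, type I interferon, immediate early, hypoxia and glycolysis, oxidative phosphorylation, cell cycle, cholesterol, LXR, unfolded protein response, ATF4, heat shock, NRF2, lysosome and alternative macrophage activation genes. Lists for cell types and quality were monocyte and macrophage, neutrophil, dendritic, B, T and NK, erythroid, stromal, mast cell and basophil, megakaryocyte and endothelial markers, and mitochondrial, ribosomal, histone and sex-linked genes.

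The rule always names 14 genes of DKK1 signalling and osteoclast biology. It adds up to 12 called genes per direction with the largest change, the same direction in both pairs and a mean of at least 5 CPM in the higher group, leaving out unnamed models (Gm or Rik names) and IDs without a symbol. Where fewer than 5 pass in a direction it names the 10 with the smallest p. It further names up to 4 called members per list with the smallest p (2 if none is called), and the 2 most abundant members of each cell type and quality list. The values of some genes that the rule names are not reported. Gm10123, Gm17494, Gm28036, Gm6061, Usp49, Btbd6 and Lca5 (named from the authors' deposited tables), the models named as overlapping, the genes with opposite signs in the pairs other than Acp5 and Ctsk, Pet117, 1700047I17Rik1 and the plasma cell genes Mzb1, Derl3 and Tnfrsf17 were chosen after their values were seen.

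A fold against libraries all at 0 is a lower bound with a floor of 3 counts per library. With 1 to 3 counts, a ratio with an exact 95% counting interval is given. Shares have 95% Wilson intervals. Intervals and floors from counts cover counting error only.

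Positions and exon overlap come from GENCODE M21 (GRCm38), which holds 53706 of the gene IDs and lacks 95; the strand of the libraries is not stated, so overlap on either strand was counted. Near-identical models were sought with BLAST 2.17.0 (at least 95% identity over 100 bases and 50% of the shorter transcript). Fisher's exact test used SciPy 1.17.1 in Python 3.11.15.

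On simulated data with 200 changed genes, the model recovered 22.4% at 1.5-fold, 61.2% at 2-fold and 90.9% at 4-fold with 1 false call in 117. There were 20 false calls in 142 (14.1%) when the spread varied from gene to gene. The changed genes were drawn only from genes above a minimum mean count, so these recovery rates do not cover genes with few counts. A simulated raised list had an adjusted p of 1.24e-43 in camera with the preset correlation and 0.956 with an estimated one. Camera called 0 of 50 random lists. Genes were simulated independently, so these lists cannot show how often lists of correlated genes are called by mistake. With DKK1, the estimated correlation was 0.631 for the interferon list and 0.533 for the B cell list, far above the preset.

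The alternatives were no pairing, RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, legacy and robust quasi-likelihood, other thresholds, each library left out and other pseudocounts (0.5 and 5). Summing overlapping or near-identical models, and keeping only genes without exon overlap, were added after the data were seen, as was a test of the difference between the pairs with the treatment labels exchanged in precursor cells 2.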

Results

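RNA was sequenced from osteoclast precursor cells of wild-type C57BL/6 mice, the myeloid cells that can fuse into bone-resorbing osteoclasts. Precursor cells from 2 mice, numbered 1 and 2, were each treated for 3 h with DKK1 at 200 ng/ml or with PBS, which gave 4 libraries, 2 per treatment. DKK1 (Dickkopf-1) is a secreted antagonist of canonical Wnt signalling that binds the co-receptors Lrp5 and Lrp6, and PBS is phosphate-buffered saline, the control. The libraries held 53235399 counts (PBS, precursor cells 1), 53537927 (DKK1, precursor cells 1), 41163663 (PBS, precursor cells 2) and 46011873 (DKK1, precursor cells 2). Of 53801 genes listed, 22172, 22019, 21208 and 21257 had a count in these libraries, in the same order, and 17462 were tested.

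The first comparison asked which genes change when osteoclast precursor cells are exposed to DKK1. Nfam1, which encodes an ITAM-bearing receptor of immune cells, rose 2.24-fold (log2 1.17, 95% CI 1.04 to 1.30, n = 2 pairs; edgeR adjusted p = 0.00535), from 9458 to 21187 counts in precursor cells 1 and from 5095 to 12942 in precursor cells 2. Tnfaip3, which encodes a ubiquitin-editing inhibitor of NF-kB signalling, rose 1.79-fold (log2 0.84, 95% CI 0.68 to 1.00; edgeR adjusted p = 0.0469), from 5694 to 9790 counts and from 3597 to 7580. Ppp1r18, which encodes an actin-binding regulatory subunit of a protein phosphatase, rose 1.65-fold (log2 0.72, 95% CI 0.58 to 0.86; edgeR adjusted p = 0.0469). Ptprj, a receptor-type tyrosine phosphatase of blood cells, fell 1.46-fold (log2 -0.55, 95% CI -0.65 to -0.44; edgeR adjusted p = 0.0469), from 36575 to 25206 counts and from 25313 to 19417.

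The log2 differences in precursor cells 1 and 2 were 1.16 and 1.18 for Nfam1, 0.78 and 0.91 for Tnfaip3, 0.78 and 0.66 for Ppp1r18, and -0.54 and -0.55 for Ptprj. On mm10 (GRCm38), Nfam1 (ENSMUSG00000058099) lies on chromosome 15 from 82992973 to 83033306, Tnfaip3 (ENSMUSG00000019850) on chromosome 10 from 19000910 to 19015657, Ppp1r18 (ENSMUSG00000034595) on chromosome 17 from 35865593 to 35875596 and Ptprj (ENSMUSG00000025314) on chromosome 2 from 90429754 to 90580647. All are protein-coding genes. Nfam1 and Tnfaip3 overlap no other exon and have no near-identical model, Ptprj has 3 near-identical pseudogene models that hold few counts (its own share is 99.3%), and Ppp1r18 overlaps Ppp1r18os and Gm28033 (own share 95.1%). Summed with those models, Ptprj gave a log2 change of -0.53 and Ppp1r18 0.69, with an edgeR adjusted p of 0.0376 for each. That fit held the called genes both alone and summed, which lowers the adjusted p. Tnfaip3, with no other model, went from 0.0469 to 0.0376 in it, so the lower value is not a gain from summing.

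In total, 9 of 17462 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 7 higher and 2 lower with DKK1. An unadjusted p under 0.05 was found for 781 genes (4.47%), fewer than the share of 0.05 that tests without any effect would give. Without the pairing of the libraries, edgeR called 0 genes (116 with an unadjusted p under 0.05). Tnfaip3, Ppp1r18 and Ptprj lost their call with upper-quartile scaling (edgeR adjusted p = 0.0601, 0.0611 and 0.0601), legacy quasi-likelihood (0.131 each) and limma-voom (0.0962 each), with nearly the same log2 changes, while Nfam1 kept it (0.00753, 0.0228 and 0.0133). With the pairing, DESeq2 called 46, limma-voom called 2 (Nfam1 and Gm10123) and edgeR without the filter on low counts called 0 (911 with an unadjusted p under 0.05).

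**Figure D1:**
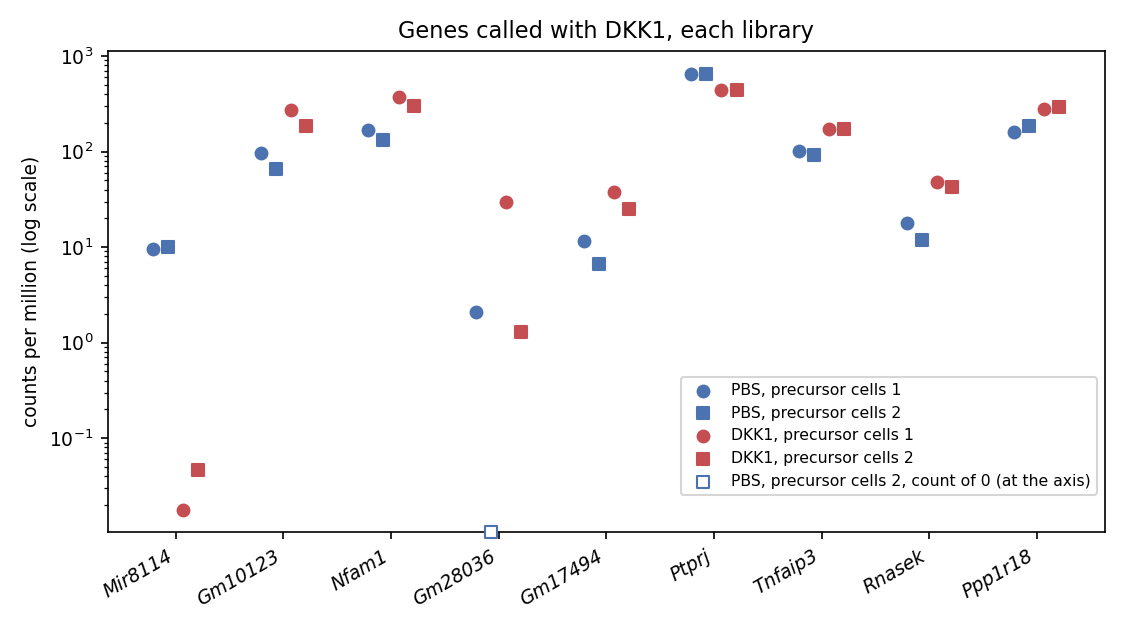
CPM (counts scaled to library size) on a log axis for the 9 genes called with DKK1, with 1 point per library; blue marks PBS, red DKK1, circles precursor cells 1 and squares precursor cells 2, and an open square at the axis marks a count of 0. In each gene both DKK1 libraries lie on the same side of the PBS library of their own pair.

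The other 5 called genes share exons or sequence with other gene models, so their own change is uncertain. Rnasek (ENSMUSG00000093989, chromosome 11, 70238124 to 70239842), which encodes ribonuclease kappa, rose 3.05-fold (log2 1.61, edgeR adjusted p = 0.0469), from 1007 to 2742 counts and from 458 to 1833. It overlaps Gm21988, and summed with it the log2 change was 1.07 with an adjusted p of 0.0534. Gm10123 (ENSMUSG00000062933, chromosome 9, 96895658 to 96896147) is a processed pseudogene resembling the cyclophilin gene Ppia and had a log2 change of 1.49 (edgeR adjusted p = 0.00397). Gm17494 (ENSMUSG00000057359, chromosome 3, 122255958 to 122293720) overlaps Gclm and Gm6061, and its log2 change was 1.80 (edgeR adjusted p = 0.0341). Gm28036 (ENSMUSG00000098950, chromosome 2, 156071845 to 156127092) spans Cpne1, Nfs1 and Rbm12 and went from 118 to 1670 counts and from 0 to 56 (edgeR adjusted p = 0.021). Mir8114 (ENSMUSG00000099227, chromosome 1, 153899926 to 153900036) lies within Glul and Teddm2 and went from 538 counts to 1 and from 390 to 2 (edgeR adjusted p = 0.00209), a ratio of 326 with a counting interval of 111 to 1580. Summed with the models they overlap or resemble, Gm10123, Gm17494, Gm28036 and Mir8114 had log2 changes of 0.06, 0.13, -0.25 and -0.08 (SE 0.04, 0.04, 0.06 and 0.06) with an adjusted p of 0.958 each, and they held 19.3%, 2.2%, 7.9% and 3% of those summed counts. Summed only with the models whose exons overlap, Gclm, Gm17494 and Gm6061 together rose (log2 1.09, SE 0.06, edgeR adjusted p = 0.00863). Gm17494 is near-identical to Ppia and Gm10123, and Gm6061 to Gm10123, so this sum does not exclude reads shared with Ppia. In precursor cells 1 and 2, Gm17494 gained 1503 and 835 counts, Gm6061 2701 and 1199, and Gclm 3525 and 1604.

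Raw counts of Ppia and of a model that shares its sequence went in opposite directions. Ppia itself, which encodes cyclophilin A, had count changes of -12857 in precursor cells 1 and -2685 in precursor cells 2, while Gm10123 gained 10012 and 5588. Ppia had a log2 change of -0.43 (edgeR adjusted p = 0.152). Gclm, the modifier subunit of glutamate-cysteine ligase, which overlaps Gm17494 and Gm6061, gained 3525 and 1604 counts (log2 0.67, edgeR adjusted p = 0.108).

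**Figure D2:**
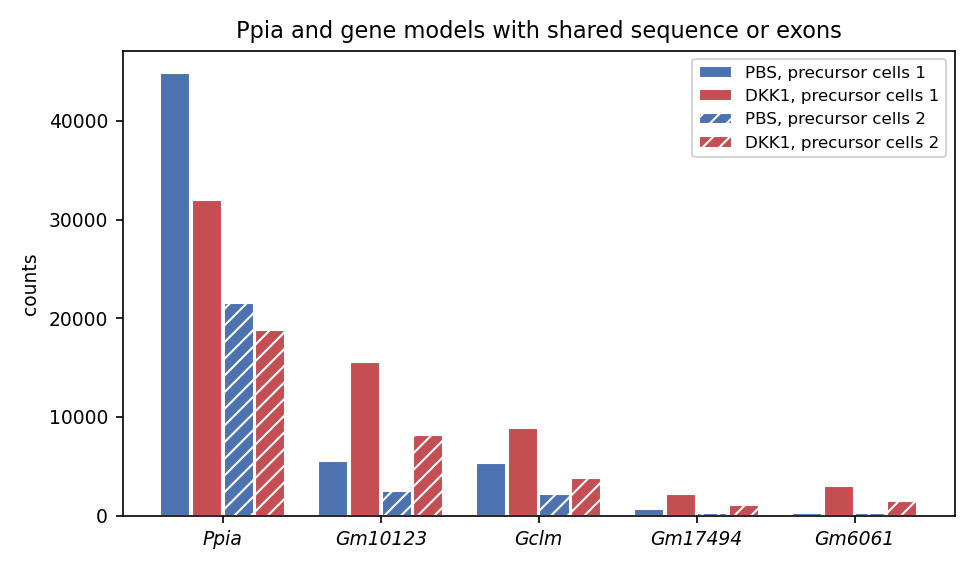
Counts for Ppia, Gm10123, Gclm, Gm17494 and Gm6061, with 1 bar per library; blue is PBS, red DKK1, plain bars precursor cells 1 and hatched bars precursor cells 2. Ppia is lower and the other 4 models are higher with DKK1 in both pairs, by raw counts.

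Among the genes with the smallest p that did not pass edgeR's test, those with a positive change were Zfp568 (log2 1.36, adjusted p = 0.0513), Gclm, Ly6c1 (log2 1.21, adjusted p = 0.146), Slirp (log2 0.95, adjusted p = 0.152), Lair1 (log2 0.62, adjusted p = 0.166) and Cyb5a (log2 0.63, adjusted p = 0.166). Ly6c1 encodes a Ly6 surface protein, Lair1 an inhibitory collagen receptor and Slirp an RNA-binding protein of mitochondria. Those with a negative change in the same edgeR test were Rbm12 (log2 -1.12, adjusted p = 0.0677), Ppia, Tlr1 (log2 -0.53, adjusted p = 0.152), Ablim1 (log2 -1.54, adjusted p = 0.166), Stau1 (log2 -0.60, adjusted p = 0.175), Lmo2 (log2 -0.59, adjusted p = 0.185), Phc3 (log2 -1.13, adjusted p = 0.27) and 1 of the 2 gene models named Raver1 (ENSMUSG00000111497; log2 -1.74, adjusted p = 0.27), which overlaps the other. Tlr1 encodes a Toll-like receptor for bacterial lipopeptides and Lmo2 a transcriptional cofactor of blood development. Rbm12 lies within the span of Gm28036.

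Of the fixed lists of Wnt targets, Wnt receptors, osteoclast genes and repressors of osteoclast differentiation, 0 members passed edgeR's test with DKK1. The DKK1 receptors had log2 changes of -0.11 (Lrp5, 95% CI -0.32 to 0.10), -0.06 (Lrp6, 95% CI -0.25 to 0.13), 0.01 (Kremen1, 95% CI -0.17 to 0.19) and 0.01 (Ckap4, 95% CI -0.17 to 0.19). Axin2, a feedback target of canonical Wnt signalling, had 12 and 10 counts in precursor cells 1 and 99 and 55 in precursor cells 2 (PBS, then DKK1), a log2 change of -0.91 with a 95% CI of -2.05 to 0.23 and an edgeR adjusted p of 0.959. Dkk1 itself was not called and had 22, 12, 0 and 10 counts in PBS 1, DKK1 1, PBS 2 and DKK1 2, so few that its change is uncertain. Of 22 canonical Wnt target genes tested, 0 were called by edgeR over all genes and 0 adjusted over the list alone. The list's median log2 change was 0.01 and its mean -0.07, with edgeR's log2 values and limma's camera giving the direction down (adjusted p = 0.448). Cd44 (log2 -0.34) and Lgr5 (log2 -1.56) had its smallest p. Of 15 Wnt receptors and DKK1-binding proteins, 0 were called (median log2 -0.06, camera adjusted p = 0.99), and Lrp4 (log2 0.54) and Ryk (log2 -0.47) had the smallest p.

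Of 27 osteoclast differentiation and resorption genes, 0 were called over all genes or adjusted over the list alone (median log2 -0.02, mean 0.02, camera direction down, adjusted p = 0.797). The log2 changes were -0.02 for Nfatc1, the master transcription factor of osteoclasts (95% CI -0.22 to 0.18), 0.02 for Tnfrsf11a, the receptor RANK (95% CI -0.12 to 0.15), and -0.02 for Csf1r, the M-CSF receptor (95% CI -0.10 to 0.06). Those of the resorption and fusion genes were 0.00 for Acp5 (95% CI -0.16 to 0.16), 0.18 for Ctsk (95% CI -0.41 to 0.76) and -0.11 for Dcstamp (95% CI -1.20 to 0.97). Mmp9 (log2 -0.22) and Itgav (log2 0.56) had the smallest p of the list. Among 11 repressors of osteoclast differentiation, 0 were called (median log2 -0.01, camera adjusted p = 0.878), with log2 changes of 0.06 for Irf8, -0.11 for Socs3 and -0.09 for Lilrb4a.

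As sets, 5 of 32 gene lists passed camera with its preset correlation, 1 up and 4 down. Type I interferon-stimulated genes were called up with DKK1: 36 of 40 had a positive change (median log2 0.08, camera adjusted p = 0.000438; adjusted p = 0.932 with an estimated correlation). Their median was 0.19 in precursor cells 1 and -0.01 in precursor cells 2, 0 members were called over all genes or adjusted over the list alone, and Irgm1 (log2 0.18) and Oas2 (log2 -0.35) had the smallest p. Without the pairing, camera gave the list the direction down when PBS 1 or DKK1 2 was left out. The PBS side then holds a larger share of precursor cells 2, in which all 40 listed genes were higher (median log2 2.59). These directions therefore decide nothing on DKK1. NF-kB target and inflammatory genes were called down, with 36 of 44 members negative (median log2 -0.06, camera adjusted p = 0.0421; adjusted p = 0.932 with an estimated correlation). Tnfaip3, which rose, was the only member called over all genes, and 1 member was called up and 1 down adjusted over the list alone. The NF-kB call ended with upper-quartile scaling (camera adjusted p = 0.0659) and a stricter filter (0.0513). It also ended without the pairing and with any 1 library left out, but such fits leave the preparations unbalanced and cannot decide on DKK1.

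The other lists called down were markers of other blood lineages. For 8 erythroid markers the median log2 change was -0.41 (camera adjusted p = 5.54e-05; adjusted p = 0.932 with an estimated correlation), and 0 were called over all genes and 3 lower adjusted over the list alone. The haemoglobin genes Hba-a1 and Hbb-bs had log2 changes of -0.46 and -0.42. For 16 B cell markers the median was -0.38 (camera adjusted p = 0.00351; adjusted p = 0.932 with an estimated correlation), -0.48 in precursor cells 1 and 0.01 in precursor cells 2, with 0 called over all genes and 2 lower adjusted over the list alone. Fcmr, the IgM receptor, had a log2 change of -0.88 and Cd79a, a chain of the B cell receptor, -0.53. For 10 mast cell and basophil markers the median was -0.24 (camera adjusted p = 0.0464; adjusted p = 0.932 with an estimated correlation), with 0 called over all genes and 1 lower adjusted over the list alone. The proteases Prss34 and Cpa3 had log2 changes of -0.61 and -0.44. Without the pairing, camera called none of the 5 lists with all 4 libraries: the adjusted p was 0.0839 for erythroid markers, 0.745 for mast cell and basophil markers and 0.984 for each of the others. With 1 library left out as well, the direction of the erythroid markers stayed down, though their call ended without PBS 2 or DKK1 1. Camera gave the direction up for B cell markers without PBS 1 or DKK1 2. It did so for mast cell and basophil markers without PBS 2 or DKK1 1. Such fits leave 1 preparation in excess on 1 side, so they cannot decide on DKK1. The mast cell and basophil call also ended with upper-quartile scaling (0.065), no filter (0.053), a stricter filter (0.0513) and limma-voom (adjusted p = 0.131). No list call with DKK1 held with an estimated correlation. With that setting camera also missed the simulated raised list (adjusted p = 0.956), so its misses neither uphold nor refute the calls. Fry, which asks whether a set's genes move on balance one way, called none (lowest adjusted p = 0.0865).

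The remaining lists were not called by camera (adjusted p from 0.272 to 0.99), and edgeR called 0 of their members over all genes. For signalling and stress lists the median log2 changes were -0.04 for immediate early genes (Ier2 -0.26, Egr1 -0.37), 0.03 for unfolded protein response genes (Sel1l 0.30, Dnajb11 0.12), -0.01 for ATF4 and amino acid response genes (Cebpb 0.29, Psat1 0.37), 0.02 for heat shock genes (Hsph1 0.19, Hspa8 0.10) and -0.01 for NRF2 target genes (Gclm 0.67, Ftl1 -0.08). The ATF4 list had an adjusted p of 0.0265 in fry's test for change in either direction, and 1 NRF2 target was higher adjusted over the list alone. For metabolic and growth lists they were -0.04 for hypoxia and glycolysis genes (Gapdh 1.22, Hk1 -0.26), 0.02 for oxidative phosphorylation genes (Cox4i1 0.44, Ndufa4 0.26), 0.01 for cell cycle genes (Nusap1 0.26, Birc5 0.24), 0.01 for cholesterol biosynthesis and uptake genes (Sqle 0.20, Msmo1 0.25), 0.01 for LXR target genes (Scd2 0.15, Scd1 -0.34) and 0.02 for lysosome and vacuolar ATPase genes (Npc2 0.07, Ctsl 0.12). Gapdh overlaps Iffo1, has many processed pseudogenes in mouse and was at only 26.7 and 16.4 CPM in PBS, so its value is uncertain. Median and mean differed in sign for the hypoxia list (mean 0.04), the LXR list (mean -0.09), the heat shock list (mean -0.002), the NRF2 list (mean 0.01), the dendritic list (mean 0.01) and the histone list (mean 0.09).

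For cell type and quality lists the medians were -0.07 for alternative macrophage activation genes (Socs2 -0.68, Flt1 -0.20), 0.01 for monocyte and macrophage markers (Cx3cr1 -0.48, Ccr2 0.24), -0.04 for neutrophil and granulocyte precursor markers (Lcn2 -0.23, S100a9 0.12; 1 lower adjusted over the list alone), -0.10 for dendritic cell markers (Cd74 -0.21, Ccr7 -0.59) and -0.17 for T and NK cell markers (Cd247 -0.42, Trac -1.48). They were 0.05 for stromal and osteoblast markers (Ibsp 1.74, Col1a2 0.34), -0.04 for megakaryocyte markers (Treml1 -0.15, Rap1b 0.06), -0.04 for endothelial markers (Emcn 0.72, Pecam1 -0.15; camera direction up), 0.03 for mitochondrially encoded genes (mt-Nd4l 0.13, mt-Nd5 0.06), 0.01 for cytosolic ribosomal protein genes (Rpl30 0.37, Rpl18 -0.24), -0.05 for replication-dependent histone genes (Hist1h2ae and Hist1h2ac 1.03 each) and 0.03 for sex-linked genes (Ddx3y 0.32, Xist 0.09; camera direction down).

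Across all tested genes, the log2 changes with DKK1 in precursor cells 1 and 2 were nearly unrelated: Pearson's correlation was 0.006 (-5e-04 to 0.0305 with other pseudocounts), Spearman's 0.0384, and 52.1% of genes had the same sign. These values are across genes, which are not independent replicates. The authors' deposited tables compare 1 DKK1 library with 1 PBS library each and call 122 genes in precursor cells 1 (66 up, 56 down, of 13253 listed) and 130 in precursor cells 2 (71 up, 59 down, of 13175 listed). Of 12562 genes in both of the authors' deposited tables, 13 were called up in both, where independent lists would share 0.311, and 2 down in both, where they would share 0.218. A further 8 genes of the authors' deposited tables were called in opposite directions, 3 up then down and 5 down then up, where independent lists would share 0.272 and 0.25. Nfam1, Ly6c1, Zfp568, Usp49, Btbd6, Rnasek and Gm10123 were up in both of the authors' deposited tables and Lca5 was down in both. In the authors' deposited tables Nfam1 had log2 ratios of 1.16 and 1.18 and Ly6c1 1.53 and 1.04.

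**Figure D3:**
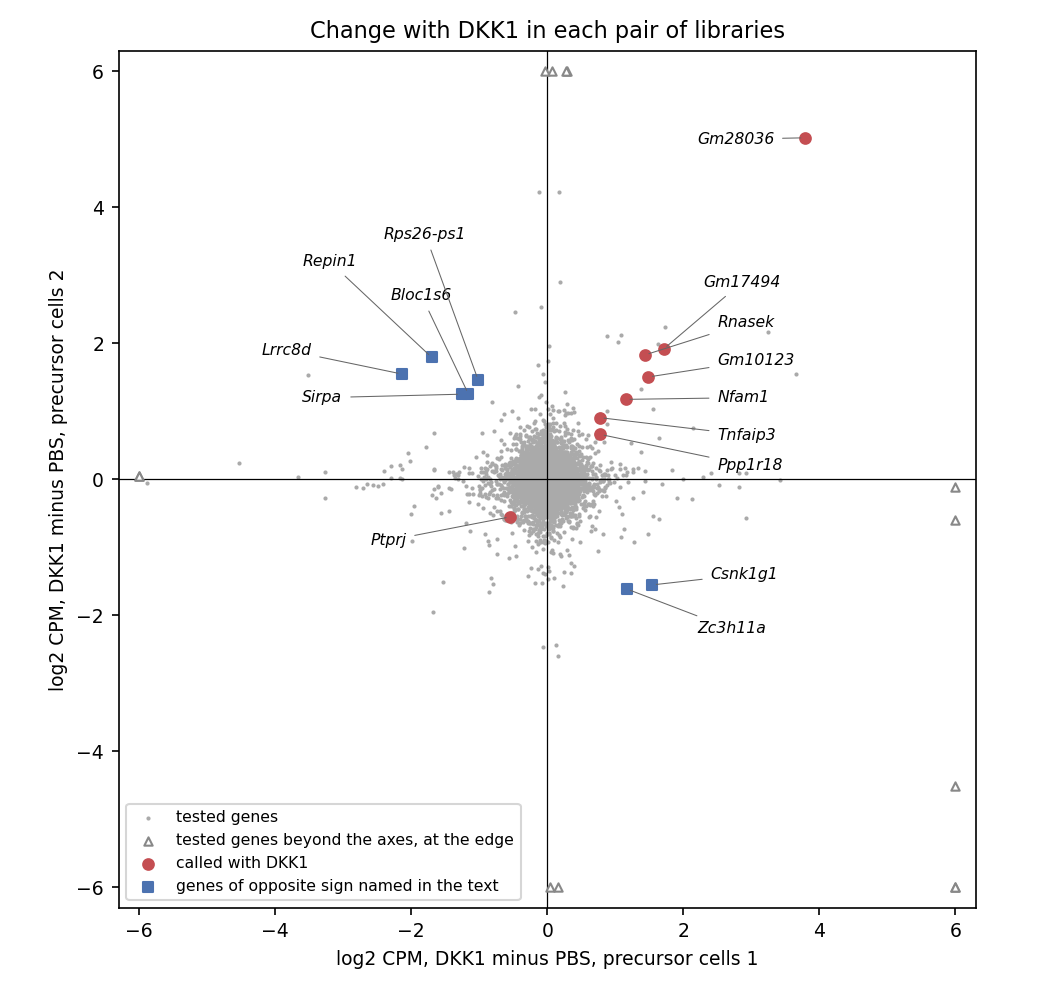
Log2 difference in CPM, DKK1 minus PBS, in precursor cells 1 (horizontal) against precursor cells 2 (vertical) for 10795 genes with a mean of at least 5 CPM; red circles are called genes, blue squares 7 genes with opposite signs, and 13 genes beyond the axes sit at the edge as triangles. Nfam1 lies at 1.16 and 1.18, and Sirpa at -1.26 and 1.25.

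The second comparison asked how far the precursor cells numbered 2 differed from those numbered 1, as a scale for the effect of DKK1. Precursor cells 2 had much higher type I interferon-stimulated transcripts: all 40 listed genes were higher (median log2 2.59), among them the antiviral genes Mx1 (13.3-fold), Rsad2 (11.8-fold) and Cmpk2 (11.7-fold) and the chemokine Cxcl10 (10.6-fold). Proliferation genes were lower, with 34 of 38 cell cycle genes down (median log2 -0.84), such as Mki67 (1.76-fold) and Mcm5 (2.36-fold). Sex-linked genes were opposite: Xist, the X-inactivation RNA of female cells, had 10 and 4 counts in precursor cells 1 and 35338 and 42589 in precursor cells 2 (PBS, then DKK1). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in precursor cells 2 and were at least 880-fold, 832-fold, 403-fold and 304-fold lower there. The list of 5 sex-linked genes was called (1 higher, 4 lower; camera adjusted p = 9.26e-06; adjusted p = 0.676 with an estimated correlation), with a median of -8.65 when genes at 0 are set to their bound; with limma-voom its adjusted p was 0.053.

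In this comparison edgeR called 5913 of 17462 genes (33.9%) at an adjusted p under 0.05, 3129 higher and 2784 lower in precursor cells 2, and 7763 had an unadjusted p under 0.05. The SD across genes of the log2 difference was 0.817 between precursor cells 2 and 1 in PBS, against 0.286 and 0.302 for DKK1 against PBS within them. Each side holds 2 libraries of the same cells, so the test compares these preparations and not a factor such as sex or substrain, and Xist overlaps Tsix and other models. The labels give C57BL/6 without a substrain, and whether the mice shared a genetic background was not tested here. Without a filter on low counts 3509 genes were called.

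The largest differences were immunoglobulin and single genes near 0 on 1 side. Leaving out unnamed gene models, the 12 called genes with the largest fitted increase were all immunoglobulin variable segments with 0 counts in precursor cells 1: Ighv5-4 (at least 863-fold), Igkv3-4 (at least 839-fold), Ighv1-59 (at least 801-fold), Ighv1-74 (at least 721-fold), Igkv3-2, Ighv1-85, Ighv1-75, Igkv2-112, Ighv14-3, Ighv2-3, Ighv1-39 and Ighv5-16 (at least 387-fold). Such segments belong to families of related sequence, so the counts of any 1 segment are uncertain. Ifi202b, an interferon-inducible gene, had 4654 and 5545 counts in precursor cells 1 and 0 in precursor cells 2 (at least 1230-fold lower), against the direction of all 40 listed interferon genes. Hal, which encodes histidine ammonia-lyase, had 10019 and 9225 counts against 16 and 10 (531-fold lower, edgeR adjusted p = 3.59e-06). Cacna1a (65.4-fold lower), Shc4 (62.5-fold lower), Pde4c, Plekha7 and Rag1 were also among the 12 with the largest decrease, as were the Y-linked genes, with 4, 5 and 8 counts of Pde4c, Plekha7 and Rag1 in both libraries of precursor cells 2 together. The remaining gene of these 12 was 1 of the 2 gene models named Map2k7 (ENSMUSG00000109061). It overlaps the other and had 971 and 18 counts in precursor cells 1 and 0 in precursor cells 2.

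By camera, 13 of 32 lists differed between the preparations, 6 up and 7 down. None held with an estimated correlation (camera, lowest adjusted p = 0.672), not even the interferon genes, all 40 of them called higher. That setting thus decides nothing here. Fry called 1 list, neutrophil and granulocyte precursor markers (adjusted p = 0.00494), and its test for change in either direction called 26. The 40 interferon genes had a camera adjusted p of 2.55e-133 (adjusted p = 0.672 with an estimated correlation) and the 38 cell cycle genes 2.59e-11 (adjusted p = 0.672 with an estimated correlation). In the cell cycle list Ccnb1 (2.85-fold lower) and Rrm1 (2.31-fold lower) were among the lowest p. Adjusted over the list alone, 40 interferon genes were higher and 35 cell cycle genes lower.

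Mitochondrially encoded, ribosomal protein, NRF2 target and cholesterol genes were mostly lower in precursor cells 2. All 13 mitochondrially encoded genes were lower (median log2 -0.86, camera adjusted p = 2.59e-10; adjusted p = 0.672 with an estimated correlation), such as mt-Cytb (log2 -1.05), mt-Nd1 (log2 -1.02), mt-Co3 (log2 -0.87) and mt-Co2 (log2 -0.76). Of 41 cytosolic ribosomal protein genes, 39 were lower and 1, Rpl30, was higher (median log2 -0.59, camera adjusted p = 8.45e-11; adjusted p = 0.672 with an estimated correlation), with Rpl10a at log2 -1.03, Rpsa at -0.84 and Rps2 at -0.84. Of 22 NRF2 target genes, which defend against oxidants, 14 were lower and 2 higher (median log2 -0.39, camera adjusted p = 1.17e-05; adjusted p = 0.672 with an estimated correlation), including Gclc (log2 -1.93), Txnrd1 (log2 -1.52), Hmox1 (log2 -1.29) and Ftl1 (log2 -0.35). Of 23 cholesterol biosynthesis and uptake genes, 16 were lower and 1 higher (median log2 -0.53, camera adjusted p = 0.000363; adjusted p = 0.672 with an estimated correlation), among them Cyp51, Fdps and Sqle (log2 -0.90, -0.87 and -0.87). Adjusted over the list alone, 13 mitochondrial, 39 ribosomal, 14 NRF2 and 17 cholesterol genes were lower and 0, 1, 2 and 1 higher.

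Myeloid markers were higher in the balance. Of 20 monocyte and macrophage markers, 13 were higher and 5 lower (median log2 0.68, camera adjusted p = 0.000173; adjusted p = 0.676 with an estimated correlation). Ly6c2 of inflammatory monocytes was 7.16-fold and Ms4a7 3.32-fold higher, while Cd14 was 2.83-fold and the lysozyme gene Lyz2 1.72-fold lower. Of 18 neutrophil and granulocyte precursor markers, 15 were higher and 2 lower (median log2 0.72, camera adjusted p = 2.54e-06; adjusted p = 0.672 with an estimated correlation), with the granule genes Ltf (2.80-fold), Ngp (2.21-fold) and Fcnb (3.64-fold) higher and Chil1 (3.28-fold) lower. Of 16 dendritic cell markers, 8 were higher and 5 lower (median log2 0.38, mean -0.14, camera direction up, adjusted p = 0.000914; adjusted p = 0.676 with an estimated correlation). The MHC class II genes H2-Aa (7.65-fold), H2-Ab1 (6.63-fold), Cd74 (4.42-fold) and H2-Eb1 (3.62-fold) were higher. Of 31 lysosome and vacuolar ATPase genes, 17 were higher and 1 lower (median log2 0.19, camera adjusted p = 0.0373; adjusted p = 0.676 with an estimated correlation), such as Npc2, Ctsz and Ctsb (log2 0.87, 0.79 and 0.47). Of 11 endothelial markers, 5 were higher and 1 lower (median log2 0.60, camera adjusted p = 0.0373; adjusted p = 0.676 with an estimated correlation), with Kdr at log2 2.75, Robo4 at 3.06, Eng at 1.22 and Pecam1 at 0.50. Adjusted over the list alone, 13, 15, 8, 18 and 6 genes of these lists were higher and 5, 2, 5, 3 and 1 lower, in the same order. The dendritic call ended with limma-voom (adjusted p = 0.242) and, without the pairing, without PBS 2 (0.524) or DKK1 2 (0.506). The lysosome and endothelial calls ended with a stricter filter (adjusted p = 0.0797 and 0.0533) and, without the pairing, without PBS 1 (0.0965 and 0.0504) or DKK1 1 (0.055 and 0.0601).

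B cell markers went the other way. Of 16, 14 were lower and 2 higher in precursor cells 2 (median log2 -2.78, or -2.76 with the 2 genes at 0 set to their bound; camera adjusted p = 0.000591; adjusted p = 0.71 with an estimated correlation), with the same counts adjusted over the list alone. Pax5, the B cell transcription factor, was 14.9-fold lower, while Jchain, which joins IgA and IgM in antibody-secreting cells, was 193-fold higher (169 and 129 counts against 19488 and 22255). The recombinase gene Rag1 had 1047 and 756 counts in precursor cells 1 and 0 and 8 in precursor cells 2.

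The inflammatory, Wnt and osteoclast lists held called members in both directions and were not called by camera (adjusted p from 0.0989 to 0.956 over the 19 lists not called). Of 44 NF-kB target and inflammatory genes, 16 were higher, such as Nos2 (17.8-fold) and Ccl5 (15.5-fold), and 15 lower, such as Cxcl3 (10.3-fold) and the scavenger receptor Marco (5.88-fold), with a median log2 of -0.05. Of 22 Wnt target genes, 5 were higher and 5 lower (median log2 -0.39), among them Axin2 (log2 3.28), Jun (log2 0.41), Myc (log2 -1.98), Fosl1 (log2 -1.68) and Ccnd1 (log2 -0.66). Of 15 Wnt receptors and DKK1-binding proteins, 4 were higher and 2 lower (median log2 0.06), with Lrp4 at log2 1.71, Ckap4 at 1.17, Kremen1 at -0.44 and Fzd7 at -0.57; Lrp5 (0.03) and Lrp6 (-0.02) were not called. Of 27 osteoclast genes, 10 were higher and 7 lower (median log2 0.01, mean -0.16, camera direction up). Ctsk (log2 2.27), Clcn7 (0.87), Tcirg1 (0.85), Acp5 (0.42), Csf1r (0.37) and Nfatc1 (0.32) were higher and Dcstamp (-2.04) and Mmp9 (-0.87) lower, while Tnfrsf11a (0.01) and Irf8 (-0.13) were not called. Of 11 repressors of osteoclast differentiation, 5 were higher and 3 lower (median log2 -0.13, mean 0.26, camera direction up), with Socs1 at 2.88, Rbpj at 1.03, Id1 at -0.75 and Lilrb4a at -0.57. Dkk1 (log2 -1.28) was not called. Adjusted over the list alone, 18, 5, 4, 10 and 5 genes of these lists were higher and 18, 7, 2, 9 and 3 lower, in the same order, and the osteoclast median was -0.04 under upper-quartile scaling.

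The other stress, metabolic and macrophage lists also split. Of 31 immediate early genes, 8 were higher and 13 lower (median log2 -0.24; Klf2 -1.44, Egr2 -2.15, Jund -0.70 and Atf3 0.77). Of 26 ATF4 targets, 7 were higher and 8 lower (median 0.03, mean -0.03; Slc7a11 -2.15, Slc7a1 -1.22, Psat1 -1.19 and Vldlr -1.92). Of 21 unfolded protein response genes, 4 were higher and 9 lower (median -0.19; Herpud1 -0.82, Sdf2l1 -0.54, Edem1 0.43 and Ddit3 0.89), and of 16 heat shock genes, 3 and 8 (median -0.15; Hspd1 -0.80, Hsp90aa1 -0.49, Dnaja1 0.51 and Hspa8 0.36). Of 29 hypoxia and glycolysis genes, 9 were higher and 6 lower (median 0.06; Hk2 0.99, Vegfa 1.25, P4ha1 0.71 and Pgk1 -0.56). Of 36 oxidative phosphorylation genes, 2 were higher and 11 lower (median -0.18; Cycs 0.52, Atp5a1 -0.48, Cox7b -0.58 and Ndufa4 -0.56). Of 11 LXR targets, 5 were higher and 2 lower (median 0.27; Abcg1 1.22, Nr1h3 0.51, Scd2 -1.37 and Scd1 -2.04), and of 15 alternative macrophage activation genes, 6 and 5 (median 0.33, mean -0.16, camera direction down; Chil3 1.37, F13a1 -1.38, Mrc1 -1.43 and Stab1 -0.59). Adjusted over the list alone, 9, 7, 5, 3, 11, 3, 5 and 6 genes of these lists were higher and 14, 9, 11, 8, 8, 14, 2 and 5 lower, in the same order, and the ATF4 median was -0.02 under upper-quartile scaling.

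Among the remaining lineage and quality lists, 5 of 8 erythroid markers were higher and 1 lower (median log2 0.75; Hbb-bs 0.96, Hbb-bt 1.01, Hba-a1 0.54 and Tfrc -1.13), and 4 of 10 mast cell and basophil markers were higher and 1 lower (median 0.79; Prss34 1.05, Cpa3 1.91, Fcer1a 4.97 and Kit 0.52). Of 18 stromal and osteoblast markers, 5 were higher and 1 lower (median 0.80; Sparc 1.13, Thy1 2.11, Kitl 2.17 and Ibsp -3.97). Of 12 megakaryocyte markers, 0 were higher and 5 lower (median -0.20; Pf4 -1.17, Ppbp -0.48, Treml1 -0.44 and Itgb3 -0.35). Of 13 T and NK cell markers, 2 were higher and 2 lower (median 0.28, mean -0.05, camera direction down; Cd4 1.21, Il2rb 1.34 and Cd2 -2.13, with Cd8a 2.84-fold lower), and of 13 histone genes, 3 and 1 (median -0.03, mean -0.18, camera direction up; Hist1h2bc 1.46, Hist1h1c 0.63, Hist2h2aa1 3.00 and Hist1h3c -2.26). Adjusted over the list alone, 6, 4, 5, 0, 2 and 3 genes of these lists were higher and 1, 2, 1, 5, 2 and 1 lower, in the same order.

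**Figure D4:**
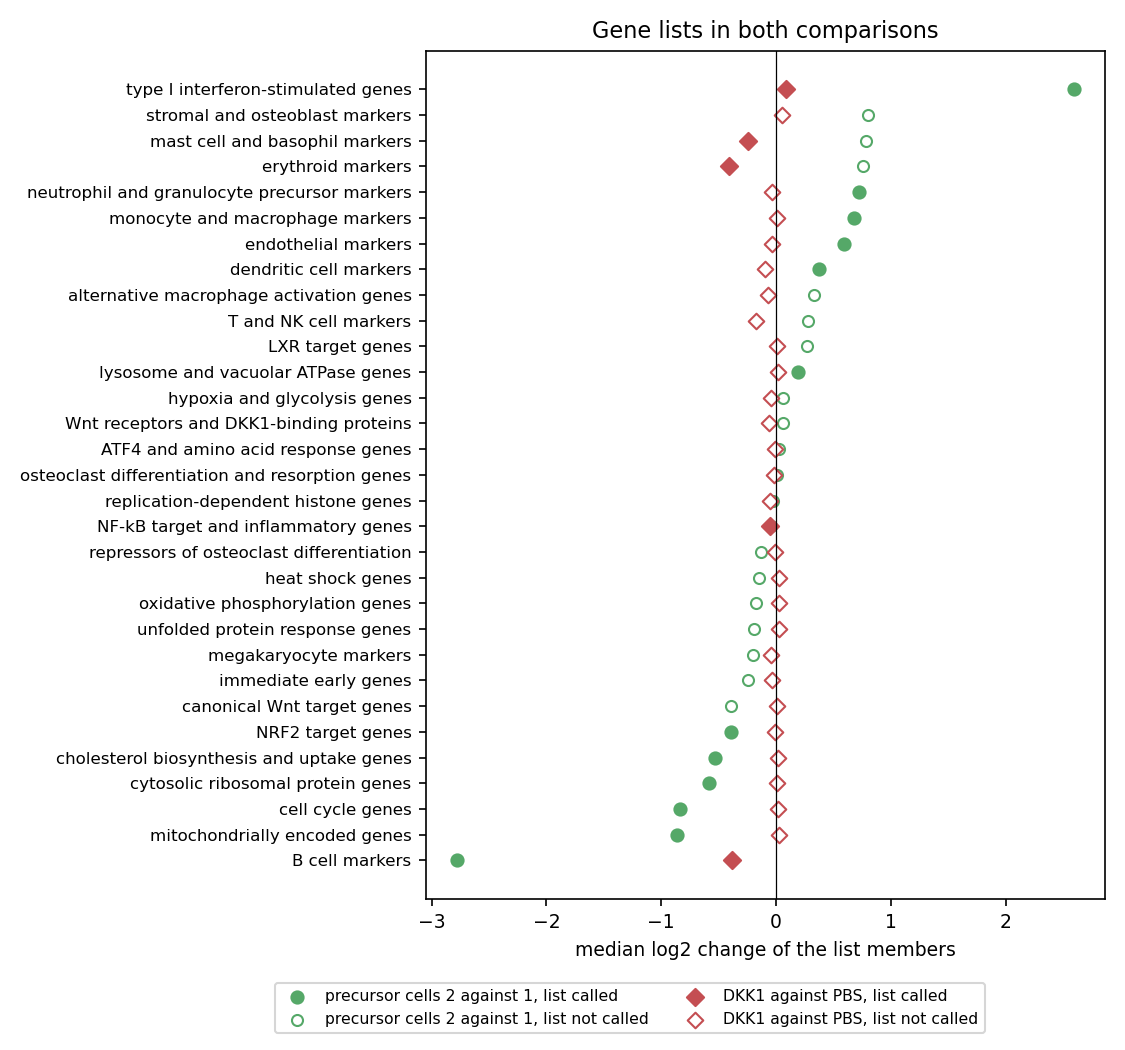
Median log2 change of each list's members in precursor cells 2 against 1 (green circles) and with DKK1 against PBS (red diamonds); filled symbols are lists called by camera with its preset correlation, open symbols lists not called, and the sex-linked list is left out. Interferon genes lie at 2.59 and B cell markers at -2.78 between the cells, while with DKK1 the lists lie between -0.41 and 0.08.

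The most abundant members of the lineage and quality lists are given in CPM for PBS 1, DKK1 1, PBS 2 and DKK1 2. Myeloid markers were at 24910, 24780, 14290 and 14680 (Lyz2), 2076, 2227, 3516 and 3616 (Mpeg1), 1377, 1310, 2972 and 2962 (Ngp) and 1353, 1427, 1845 and 2074 (S100a9). The antigen presentation genes were at 763, 606, 3099 and 2909 (Cd74) and 168, 142, 1040 and 1007 (H2-Ab1). Lymphoid markers were at 2.99, 2.27, 504 and 512 (Jchain), 201, 142, 134 and 121 (Ighm), 10.3, 12.4, 26.5 and 26.1 (Cd4) and 6.71, 7.38, 9.65 and 9.25 (Nkg7). Markers of erythroid cells and platelets were at 209, 206, 91.4 and 98.5 (Tfrc), 37, 25.6, 51.5 and 39.3 (Hba-a1), 868.4, 878, 884 and 949 (Rap1b) and 839, 775, 355 and 364 (Pf4). Stromal and endothelial markers were at 23.1, 27.2, 32.6 and 33.4 (Col1a1), 17.1, 16.6, 38.9 and 34.9 (Sparc), 36.3, 37, 84.8 and 86.2 (Eng) and 10.4, 8.93, 61.7 and 68 (Kdr). Mast cell and basophil markers were at 89.4, 94.3, 102 and 102 (Il6ra) and 73.9, 73.4, 63.5 and 56.1 (Hdc). Quality genes were at 5582, 5590, 4872 and 4936 (mt-Co1), 1112, 1166, 722 and 743 (mt-Nd5), 1168, 1146, 826 and 787 (Rplp0), 958, 931, 633 and 602 (Rpl4), 18.8, 19.1, 31.4 and 27.4 (Hist1h1c), 8.59, 9.25, 26.4 and 22.7 (Hist1h2bc), 0.177, 0.0705, 914 and 980 (Xist) and 57.3, 71.7, 0 and 0 (Ddx3y).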

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

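Of the tests in this part, those on splits of the libraries, on summed gene models, on the difference between the pairs and on shifts of genes with at least 5 CPM were chosen only after the result was seen.

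The DKK1 calls were compared with reads shared between gene models as a technical explanation: reads that only moved between models leave their summed counts unchanged. Against this as the whole cause, 2 called genes (Nfam1 and Tnfaip3) have no overlapping or near-identical model, and the sums still moved for Ptprj (log2 -0.53, 95% CI -0.64 to -0.43), Ppp1r18 (0.69, 0.55 to 0.82) and Rnasek (1.07, SE 0.10, 0.83 to 1.31, against 1.61, SE 0.13, alone), although the Rnasek sum, smaller against its SE, narrowly missed the threshold (adjusted p = 0.0534). For Gm10123 the sum moved by log2 0.06 (95% CI -0.04 to 0.16), where its own change would give 0.24 with the other models unchanged, so reads shared between gene models are a candidate cause there. They stay open for 3 genes, whose own change would move the sum by less than the distance from the sum to its 95% CI limits. The observed sums moved by 0.13 (95% CI 0.032 to 0.218) for Gm17494, -0.25 (-0.405 to -0.09) for Gm28036 and -0.08 (-0.225 to 0.062) for Mir8114. With the other models unchanged, these sums would have moved by 0.04, 0.14 and -0.09. An effect of DKK1 on Nfam1, Tnfaip3, Ptprj and Ppp1r18 is a hypothesis on 2 pairs.

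Only 2 splits keep 1 library of each cell number per group, too few for a share under 0.05: with edgeR the real split called 9 genes and the other 3, so that 1 of the 2, the real one, called as many as 9. The real and the other split called 3 and 3 with legacy edgeR, 46 and 24 with DESeq2 and 2 and 1 with limma-voom.

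Some genes shifted strongly within single pairs, often in opposite directions. Over all tested genes, 896 shifted at least 1.4-fold the same way in both pairs and 837 in opposite ways, a ratio of 1.07 (95% exact interval 0.97 to 1.18), where a treatment effect was predicted to give at least 2 and its absence at most 1.5. Of these, 666 and 650 had a mean under 1 CPM, near the floor, where counting error is large, so the ratio does not decide on DKK1. Among genes with a mean of at least 5 CPM, the counts were 65 and 40 (ratio 1.62, interval 1.08 to 2.47). This minimum was not part of the prediction. Of these genes, those without exon overlap gave 35 and 22 (ratio 1.59, interval 0.91 to 2.85), an interval that includes equal counts. Both intervals hold 1.5 and 2, which leaves an effect of DKK1 on these genes open. Genes called in the authors' deposited tables overlapped exons of other genes in 49.8% of cases against 38% (odds ratio 1.62, Fisher's exact two-sided p = 0.000346), so reads shared between gene models are a candidate cause for part of them. This test and the exact intervals above take genes as independent, which models that share reads are not, so they overstate certainty.

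The genes below stood out because both pairs went opposite ways, beyond counting error. The difference between the pairs was tested with edgeR by exchanging the treatment labels in precursor cells 2. The log2 differences in precursor cells 1 and 2 were -1.26 and 1.25 for Sirpa, -2.14 and 1.55 for Lrrc8d, -1.71 and 1.81 for Repin1, -1.16 and 1.26 for Bloc1s6 and -1.02 and 1.46 for Rps26-ps1. They were 1.55 and -1.56 for Csnk1g1, 1.17 and -1.61 for a Zc3h11a model, 1.24 and -3.06 for AL732309.1, 0.84 and -0.17 for Ctsk and 0.10 and -0.11 for Acp5. Sirpa, a receptor for CD47 on myeloid cells, had 72507 and 30427 counts in precursor cells 1 and 27825 and 74462 in precursor cells 2 (PBS, then DKK1), and the difference between its pairs passed the test (adjusted p = 0.02). It did not pass for the others of these genes (adjusted p from 0.1 for Csnk1g1 upward). The same edgeR test called 2 further genes, Pet117 (adjusted p = 0.02; 654 and 1 counts, then 1 and 299; it overlaps Kat14) and 1700047I17Rik1 (adjusted p = 0.0371; 0 and 1970 counts, then 1542 and 0).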

How the results depend on the processing

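Summing or leaving out overlapping models was chosen after seeing the data; the other alternatives here were planned.

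Summing overlapping and near-identical models was done for the 9 genes called with DKK1 only, and 4 of these still passed. Among these 4, Nfam1 and Tnfaip3 have no such model, so nothing was summed for them and their pass does not test summing. Of the 7 called genes with such a model, 2 (Ptprj and Ppp1r18) still passed. The DKK1 count (9 genes) was 0 with no replicate block for the pair, 5 with upper-quartile scaling, 0 with no filter, 15 with a stricter filter, 46 with DESeq2 (8 of the 9 among them), 2 with limma-voom, 3 with legacy quasi-likelihood and 14 at an adjusted p under 0.1. It was 0 to 0 with each library left out, without the pairing (104 to 171 genes with an unadjusted p under 0.05). RLE scaling (10), robust fitting (13), a minimum log2 of 1 (6), loci (7, among them the locus of Gclm, Gm17494 and Gm6061, and Gm10123) and genes without exon overlap (10) stayed within 1.5 times. The causes were not tested.

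The count between cells (5913) was 3509 with no filter and 3916 to 4891 with each library left out, lowest without DKK1 2 (3916) and PBS 2 (3926); the cause was not tested. Its model without the cells' term could not be fitted, since that term is the comparison. Under upper-quartile scaling the calls split 2798 higher and 3144 lower.

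Lists called with DKK1 (5) were 0 with no replicate block, 3 with upper-quartile scaling, 3 with a stricter filter, 0 with an estimated correlation and 5 to 9 with each library left out: 9 without PBS 1, 8 without PBS 2 and 9 without DKK1 2. Those between the cells (13) were 0 with an estimated correlation, a setting that also missed the simulated raised list and so decides neither comparison. Without the pairing, a library left out leaves 1 cell preparation in excess on 1 side, so these fits cannot decide on DKK1. The interferon list's adjusted p was then 1.62e-17 to 7.41e-11, down without PBS 1 (7.41e-11) and DKK1 2 (4.27e-11). For B cell markers it was 2.64e-07 to 0.122, up without PBS 1 (0.00407) and DKK1 2 (0.122). For mast cell and basophil markers it was 0.0127 to 0.97, up without PBS 2 (0.97) and DKK1 1 (0.853). The lone library is assumed to vary like the others. Lists were not run with DESeq2, legacy or robust fits.

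The correlation between the pairs (0.006) ranged from -5e-04 (pseudocount 0.5) to 0.0305 (pseudocount 5), so its sign depends on the pseudocount; no spread was computed for it. Of 1874 comparisons of named genes, 1755 kept their side of the threshold, 95 lost and 24 gained a call, and 0 reversed. Among the 1755 are 82 in which an uncalled gene changed sign.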

Other observations

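The immunoglobulin group and the tests in this part were chosen only after the result was seen.

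Most immunoglobulin genes were higher in precursor cells 2. The IgM constant region gene Ighm, whose CPM are given above, was not. Of 202 tested immunoglobulin genes, 189 were higher, 3 lower and 10 not called (median log2 6.61, or 6.30 with genes at 0 set to their bound). They held 0.042% of counts in PBS 1 (95% Wilson interval 0.0415 to 0.0426), 0.0301% in DKK1 1 (0.0296 to 0.0305), 1.56% in PBS 2 (1.55 to 1.56) and 1.51% in DKK1 2 (1.51 to 1.51). With DKK1 0 of them were called by edgeR.

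A hypothesis is that plasma cells among precursor cells 2 could be the source. All 4 plasma cell genes tested were higher and called: Jchain (log2 7.59), Mzb1 (log2 2.67), Derl3 (log2 3.00) and Tnfrsf17 (at least 15.2-fold); Jchain is also in the B cell list. A higher share of all B lineage cells is argued against by the B cell markers, whose median log2 was -2.78. No sort or gate is known here that would remove such cells, and the levels of Jchain (504 and 512 CPM against 2.99 and 2.27) and Mzb1 are from 1 preparation each.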
